A study of Rattus norvegicus with 36 samples.

How the data were processed

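The series holds 36 samples: 16 GR ChIP-seq libraries, 16 pCREB ChIP-seq libraries and 4 inputs, from rat hippocampus. Per the labels' protocols, chromatin was fixed with 1% formaldehyde, 4 hippocampi of 2 rats were pooled for each library, the chromatin was divided between an anti-GR and an anti-phospho-CREB antibody, and libraries were amplified with 15 PCR cycles and sequenced as single reads in runs of 51 bp and 65 bp. The labels give the libraries of the 4 conditions (untrained vehicle, untrained corticosterone, trained vehicle, trained corticosterone) the lane numbers 5, 6, 7 and 8. Lane and condition therefore cannot be told apart. Replicates are separate pools of rats.

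Per the submitters' processing notes, the tools were BWA 0.7.10, MACS2 2.1.1.20160309, bedtools 2.26.0 and HTSeq 0.6.1-1 with genome build rn6; their parameters are not given in the sources used here. The deposited values are raw read counts per region and library, with no normalization, in separate lists for GR and pCREB, per the file headers and the values. Per the names of the peak calls beside each region in the deposited table, regions were merged from peaks called in each library. When tested, every one of the 20029 regions had a call in at least 3 of the 4 libraries of some condition. A region can thus be listed because of its signal in these libraries, so that the lists are not independent of the comparisons. Regions with calls in 3 or more libraries numbered 321, 1887, 1748 and 4500 for GR in the order of conditions above, and 5515, 11091, 9484 and 7150 for pCREB. The inputs have no columns in the table analysed, so that enrichment over input was not analysed here.

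The 16 count columns carry the condition number and letter of the libraries, and hold the GR libraries beside GR regions and the pCREB libraries beside pCREB regions. In a check, regions with a call in a library were compared with its column: the library's own column was highest for 15 of 16 GR and 16 of 16 pCREB libraries, the exception being GR untrained corticosterone B. The 3 mitochondrial regions of each list took 7.655% to 22.946% of the counted reads of GR libraries and 2.047% to 8.653% of those of pCREB libraries. No library pair of a condition was a duplicate: over 24 pairs per antibody, the lowest chi-square per degree of freedom was 1.79 for GR and 1.3 for pCREB.

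Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust dispersions, TMM normalization on the tested regions, filterByExpr by condition). One model with 4 groups was fitted to the 16 libraries of each antibody, with no covariates. An adjusted p (Benjamini-Hochberg) under 0.05 was called. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM are edgeR's normalized counts, relative to the reads in the tested regions after TMM. GR and pCREB were compared in one model of 32 libraries at 4227 regions that overlap one to one, of which 4225 were tested. The model written before the data were examined did not foresee separate region lists of different width. Counts were therefore divided by relative region width before library totals and TMM factors were computed. A first fit, which applied widths only after TMM, was replaced once its shift towards GR (median log2 fold change 0.212) was seen; its counts and those without any width correction are given with the alternatives. Total reads were compared with exact two-sided permutation tests of log2 totals (scipy 1.17.1). Overlaps were computed with GenomicRanges 1.54.1, and shares have exact Clopper-Pearson intervals, which cover counting error only. Set tests used camera with its preset correlation, camera with an estimated correlation, and fry (limma 3.58.1).

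Groups, tests, the naming rule and the first list of alternatives were fixed before the data were examined. The rule named the 10 regions with the largest rise and the 10 with the largest fall for each average corticosterone effect and for GR against pCREB, and 5 of each direction for other comparisons. A named region had to pass the test, have a mean log2 CPM above the median of the tested regions, and show no overlap between the compared groups of libraries. Where fewer than 3 passed, the 3 with the smallest p were named as not passing. The tests were run on simulated counts with 200 changed regions, made from the means, dispersions and library sizes of the real libraries. They were drawn independently for each region.

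Pairing was checked before fits were compared. Deviations from the condition mean correlated at -0.2 to 0.49 between GR libraries with the same letter in different conditions (median 0.07, 11 of 24 pairs above 0.1). For pCREB the range was -0.34 to 0.51 (median 0.12, 13 of 24). Libraries with different letters in different conditions were not compared, so that the check does not decide whether letters pair libraries across conditions. GR and pCREB libraries of the same pool are paired by the protocol. Their deviations at the shared regions correlated with a median of 0.09 (-0.03 to 0.29), against a median of -0.01 for other pools of the same condition.

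The alternatives were DESeq2 1.42.0, scaling by total count, no filter, fits of only the groups compared, the replicate letter or the chromatin pool as a block, an adjusted p under 0.01, leaving out each library in turn, and stricter overlaps. Others were added after seeing the data: leaving out libraries with calls in under 15% of regions, leaving out mitochondrial, Y, unplaced and strongly varying chromosome 7 regions, 1 surrogate variable (sva 3.50.0), the first principal component of the regions that overlap a region of the other antibody as a covariate, loess offsets, TMM factors from shared regions, and adjustment over regions outside the list of the other antibody. Genes were not assigned to regions, and the planned gene lists and sequence motifs were not analysed here, since no genome or annotation of build rn6 was used here. Regions are given by their coordinates in the deposited table. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.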

Results

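Binding of the glucocorticoid receptor (GR), a transcription factor that is activated by glucocorticoid hormones such as corticosterone, and of CREB phosphorylated by kinase signalling (pCREB) was measured by ChIP-seq in the hippocampus of male Sprague-Dawley rats. The series is about how glucocorticoids strengthen memory formation. Rats had been trained or left untrained and had received corticosterone, the main glucocorticoid of rats, or vehicle, which gave 4 conditions. Each library came from the pooled chromatin of 4 hippocampi of 2 rats, and each pool was split between both antibodies, so that every condition had 4 GR libraries and 4 pCREB libraries. The libraries of a condition are named A to D below.

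The counts covered 5307 GR regions and 14722 pCREB regions of the rat genome build rn6, with median widths of 392 bp and 462 bp. GR libraries held 55254 to 173176 reads in their regions (mean 115048 ± 27129, SD, n = 16). The pCREB libraries were deeper, with 143219 to 562249 reads (mean 418443 ± 124058, SD, n = 16). The median region had 5 to 23 reads in a GR library and 6 to 28 reads in a pCREB library, so that single regions were measured with a large counting error. Peak calls were unevenly spread over libraries. GR untrained vehicle A and B had calls in 196 and 666 GR regions and GR untrained corticosterone B in 513, whereas GR trained corticosterone B had calls in 4849. The biological coefficient of variation between libraries of a condition was 0.312 for GR and 0.255 for pCREB.

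**Figure D1:**
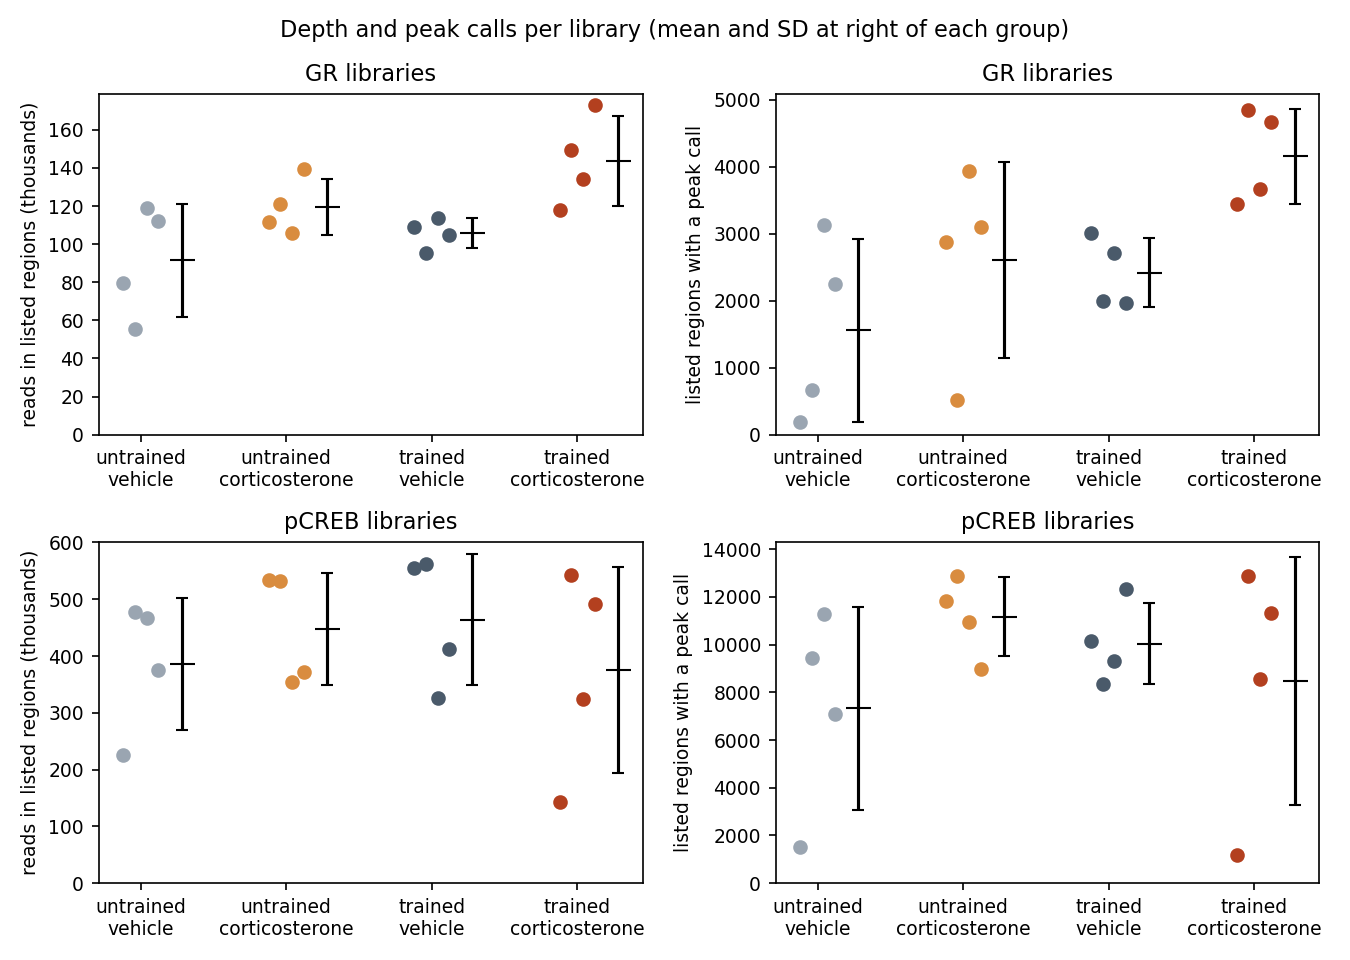
Reads in the listed regions (left) and number of listed regions with a peak call (right) for each of the 16 GR and 16 pCREB libraries, by condition. Points are libraries, and bars give the mean and SD of the 4 libraries of a condition. The trained corticosterone GR libraries have 3437 to 4849 regions with a call and the untrained vehicle GR libraries 196 to 3128.

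The first question was where corticosterone changed GR binding. Averaged over trained and untrained rats, 82 GR regions rose after corticosterone and 1 fell. The rises ranged from 1.84-fold to 17.4-fold with a median of 3.09-fold, and 26 of the 82 regions rose by more than 4-fold. The region with the highest fold, chr10:59884799-59885334, rose 17.4-fold (log2 fold change 4.12, SE 0.43, adjusted p 1.33e-05), from 45.2 ± 42.4 CPM in the vehicle libraries to 766 ± 329 CPM after corticosterone (SD, n = 8 each). It held 0 to 13 reads in the vehicle libraries and 50 to 214 reads in the corticosterone libraries. A further region of chromosome 10, chr10:16942351-16942910, rose 6.68-fold (SE of log2 0.29, adjusted p 3.88e-06), from 52.3 ± 33.6 to 343 ± 149 CPM. On chromosome 17, chr17:5971448-5971815 rose 6.65-fold from 49.5 ± 35.6 to 336 ± 126 CPM (SE of log2 0.34, adjusted p 8.08e-05).

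The other named regions rose less. Signal at chr3:2251775-2252102 rose 4.93-fold, from 49.3 ± 41.2 to 222 ± 87.5 CPM. At chr1:73760445-73760846 the rise was 4.65-fold, and at chr1:78999395-78999862 it was 4.16-fold, from 152 ± 129 to 596 ± 179 CPM. On chromosome 11, chr11:31424285-31424773 rose 3.04-fold and chr11:77467099-77467439 rose 2.96-fold. The smallest rises among the 10 named regions were 2.58-fold at chr2:9601212-9601728 and 2.34-fold at chr13:71575065-71575656, from 109 ± 36.3 to 247 ± 45.5 CPM. Adjusted p for these 7 regions lay between 0.00016 and 0.00312. The region that fell, chr10:36884312-36884683, was outside the naming rule and was looked at after its value was seen. Its signal fell by 0.86 on the log2 scale (SE 0.22, adjusted p 0.0358). Scaling by total count and TMM factors from shared regions called 0 regions lower. So did the fits without GR untrained vehicle A, untrained corticosterone D or trained corticosterone D. DESeq2 and the fit without a filter kept the call.

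**Figure D2:**
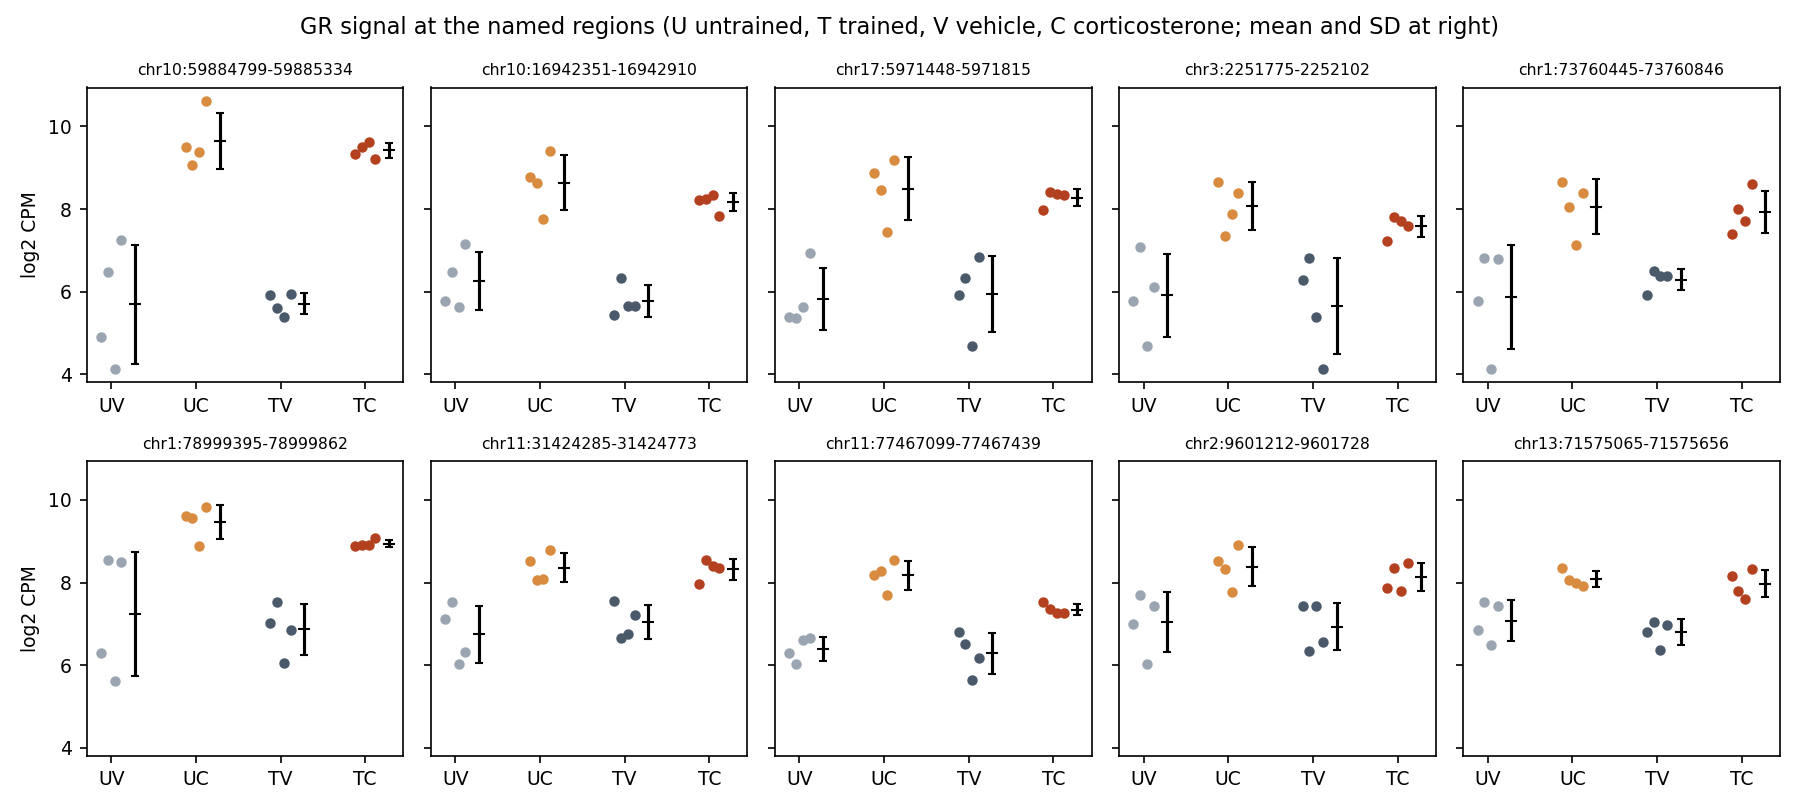
GR signal (log2 CPM) at the 10 named regions in each of the 16 GR libraries, by condition. Points are libraries, and bars give the mean and SD of the 4 libraries of a condition. In every panel the 8 corticosterone libraries lie above the 8 vehicle libraries, with rises from 2.34-fold to 17.4-fold. The naming rule required this separation. Of the 82 regions that rose, 16 had no overlap between the 8 corticosterone and the 8 vehicle libraries.

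All calls come from edgeR's quasi-likelihood test over 4968 regions with Benjamini-Hochberg adjustment, and DESeq2 called 99 higher and 3 lower, among them all 83 of edgeR's regions. The number of calls was 335 without GR untrained vehicle B and 150 without GR untrained corticosterone C, and it was 53, 54 and 53 without GR untrained vehicle A, GR untrained corticosterone D and GR trained corticosterone D. It was 125 with scaling by total count, 46 at an adjusted p under 0.01, 199 without the 3 GR libraries with few peak calls, 167 with a surrogate variable and 240 (232 higher, 8 lower) with the first principal component of the GR regions that overlap pCREB regions as a covariate.

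The regions where GR rose seldom overlapped a region of the pCREB list. No pCREB counts were available at GR regions outside that list, so that lack of overlap does not show lack of pCREB binding. Of the 82 regions, 72 did not overlap any pCREB region, although 4064 of the 4968 tested GR regions (81.8%) did. Fisher's exact test gave a difference in overlap (two-sided p 1.64e-43, odds ratio 0.0285), a comparison chosen after the results were seen. The median log2 fold change was 0.48 over the 904 tested GR regions outside pCREB regions and -0.11 over those that overlapped one. Its zero point depends on the scaling: the median over all tested regions was -0.067, and 0.027 with TMM factors from shared regions. The -0.11 therefore does not show a loss of GR signal. Fisher's test treats regions as independent; as a set, the 904 regions moved together between libraries, and their shift did not pass (camera adjusted p = 0.132 with an estimated correlation, fry adjusted p 0.22). The 10 overlapping regions that rose included chr15:58884552-58885070 (4.38-fold, SE of log2 0.34, adjusted p 0.00114) and chr19:57346524-57346864 (2.87-fold, SE of log2 0.25, adjusted p 0.00114).

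**Figure D3:**
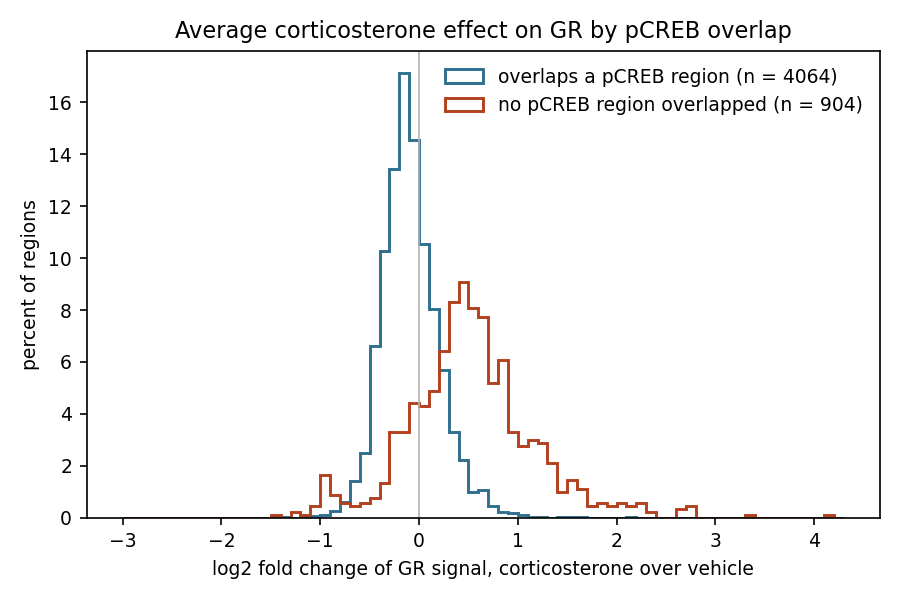
Distribution of the average corticosterone effect on GR (x axis, log2 fold change; y axis, percent of regions) for 4064 tested GR regions that overlap a pCREB region and 904 that do not. The medians are -0.11 and 0.48.

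The response was then examined separately in untrained and trained rats, and the difference between them was tested. In untrained rats 15 GR regions rose and 0 fell; in trained rats 6 rose and 0 fell, and 4 regions were called in both. All 15 and all 6 were among the 82 regions above. At chr10:59884799-59885334 the rise was 16.4-fold in untrained rats (54.7 ± 62.2 to 860 ± 471 CPM, SD, n = 4 each, adjusted p 0.00319 by edgeR) and 18.4-fold in trained rats (35.6 ± 9.24 to 671 ± 89 CPM, adjusted p 0.00313 by edgeR). At chr10:16942351-16942910 the rises were 6.39-fold and 6.98-fold, and at chr17:5971448-5971815 they were 7.64-fold and 5.79-fold. The untrained rats also showed rises of 6.24-fold at chr3:2251775-2252102 and 4.87-fold at chr15:58884552-58885070 (adjusted p 0.035 and 0.0472). In trained rats chr19:57346524-57346864 rose 3.98-fold (adjusted p 0.0162). Several of these calls lay near the threshold. In untrained rats the call at chr15:58884552-58885070 was lost in 11 of 16 fits that left out 1 library (adjusted p 0.068 to 0.249) and held only without GR untrained vehicle B, untrained corticosterone C or trained vehicle B, C or D. That at chr3:2251775-2252102 was lost in 10 of 16 (0.0623 to 0.227) and held only without those 5 libraries or untrained corticosterone B. The untrained call at chr17:5971448-5971815 was lost without GR untrained vehicle C (0.0519). The trained call there was lost in 6 of 16 (0.0655 to 0.144), without GR untrained corticosterone B, trained vehicle A or C, or trained corticosterone B, C or D. That at chr19:57346524-57346864 was lost in 5 of 16 (0.0513 to 0.125), without GR trained vehicle A, C or D or trained corticosterone B or C. The log2 fold changes stayed positive in the fits where a call was lost: 2.05 to 2.58 at chr15:58884552-58885070 (2.28 with all libraries), 2.15 to 2.8 at chr3:2251775-2252102 (2.64), 2.72 in untrained rats (2.93) and 2.15 to 2.59 in trained rats (2.53) at chr17:5971448-5971815, and 1.78 to 2.09 at chr19:57346524-57346864 (1.99).

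**Figure D4:**
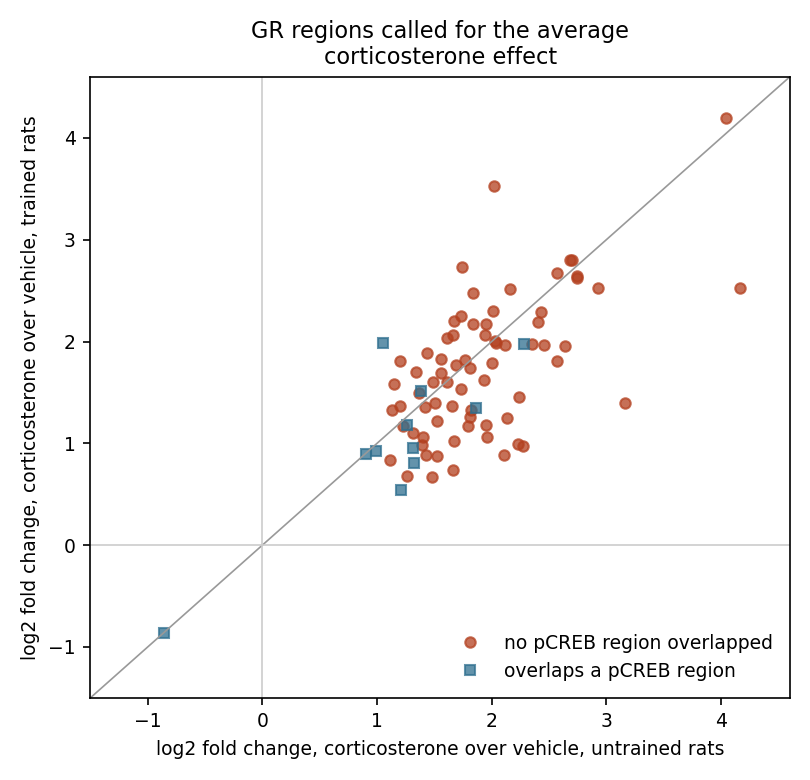
Corticosterone effect on GR (log2 fold change) in untrained rats (x axis) and in trained rats (y axis) at the 83 regions called for the average effect, with the line of equal effects. Circles are the 72 risen regions outside pCREB regions, and squares the 10 risen regions and the 1 fallen region that overlap one. All 82 risen regions lie above 0 on both axes, which their choice on the mean of both effects favours.

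All 82 regions had a positive fold change in both training states, with medians of 1.75 in untrained and 1.61 in trained rats on the log2 scale. They were chosen on the mean of both effects, which favours a positive sign in each. The test of the difference, the training by corticosterone interaction, called 0 of 4968 regions in edgeR and 0 in DESeq2. In edgeR 184 regions had an unadjusted p under 0.05, where 248 are expected by chance, and none of these was among the 82. The median SE of the interaction was 0.513 on the log2 scale, and 0.72 at GR regions outside pCREB regions. Its recovery was not simulated, so that the absence of calls does not show equal responses in both training states. The separate counts were unstable. A fit of only the 8 untrained libraries called 0 regions (363 at an unadjusted p under 0.05), a fit of only the 8 trained libraries called 56, and DESeq2 called 24 and 22. The untrained count was 225 without GR untrained vehicle B, 53 without GR untrained corticosterone C and 5 without GR untrained vehicle C, and it fell to between 7 and 9 without any of GR untrained vehicle A, untrained corticosterone A or D, trained vehicle A, or trained corticosterone A, B, C or D. The trained count was 27, 29 and 26 without GR untrained vehicle B, untrained vehicle C and untrained corticosterone C, 16 without GR trained vehicle B, and 3 without any of GR trained vehicle A or C or trained corticosterone B.

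No GR region was called for training. Of 4968 regions, edgeR called 0 in vehicle rats (152 at an unadjusted p under 0.05; DESeq2 0), 0 in corticosterone rats (184; DESeq2 0) and 0 for the average over both treatments (178; DESeq2 1). The region with the smallest p for the average training effect was chrX:47422884-47423119. Its signal was 31.9 ± 11.8 CPM in untrained and 133 ± 68.4 CPM in trained vehicle rats, and 45.7 ± 15.8 and 113 ± 10.2 CPM in untrained and trained corticosterone rats (SD, n = 4 each). The log2 fold change was 1.62 (SE 0.3, adjusted p 0.0753 by edgeR); the adjusted p was 0.0341 in DESeq2 and 0.0288 with scaling by total count, and 0.0492 and 0.0328 without GR trained vehicle A and C. It was 0.00828 with a surrogate variable and 0.0251 with the principal component as a covariate and ranged from 0.00828 to 0.352 over all alternatives, without passing in the others. Next were chr13:69493558-69493863 (log2 fold change 1.25, SE 0.3, adjusted p 0.674) and chr10:75291146-75291478 (1.03, SE 0.25, adjusted p 0.682). In vehicle rats chr2:140703967-140704398 and chr14:34011850-34012444 followed chrX:47422884-47423119, with log2 fold changes of 1.46 and 1.02 (adjusted p 0.998). In corticosterone rats chr13:69493558-69493863 had a log2 fold change of 1.94 (adjusted p 0.429), chr1:36361139-36361388 of 1.37 and chr11:79710601-79710854 of 1.81 (adjusted p 0.777 for both). For the interaction the smallest p were at chr2:140703967-140704398 (log2 -1.96), chr2:216866405-216866755 (1.96) and chr5:127586858-127587201 (-1.98), all with an adjusted p of 1.

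The same comparisons were made for pCREB, to see whether the hormone or training changed binding of the phosphorylated factor. No pCREB region passed for corticosterone. Of 14553 regions, edgeR called 0 in untrained rats (392 at an unadjusted p under 0.05), 0 in trained rats (865) and 0 for the average (709, with 728 expected by chance), and DESeq2 called 0 in each. The smallest p for the average effect belonged to chr4:71120929-71121446, with 26.3 ± 8.98 CPM in vehicle and 54.6 ± 16.4 CPM in corticosterone libraries (SD, n = 8 each; log2 fold change 0.95, SE 0.23, adjusted p 0.84 by edgeR). It was followed by chr3:123209369-123209910 (log2 fold change -0.79) and chr13:69092906-69093414 (0.64), also with an adjusted p of 0.84. In untrained rats the regions with the smallest p were chr3:123209369-123209910 (-1.14), chr14:8528996-8529305 (1.28) and chr7:79920680-79920996 (-1.24), each with an adjusted p of 1. In trained rats they were chr4:6337302-6337662 (1.41), chr4:539382-539651 (1.69) and chr17:32952915-32953659 (-1.26), each with an adjusted p of 0.78.

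Training gave no pCREB call either. Of the 14553 regions, edgeR called 0 in vehicle rats (456 at an unadjusted p under 0.05; DESeq2 0), 0 in corticosterone rats (452; DESeq2 0), 0 for the average (417; DESeq2 2) and 0 for the interaction (480; DESeq2 0). The smallest p for the average training effect was at chr7:144015523-144017621, with 251 ± 92.4 CPM in untrained and 3500 ± 4170 CPM in trained vehicle rats (SD, n = 4 each; log2 fold change 3.02, SE 0.59, adjusted p 0.848 by edgeR). Trained vehicle B and D held 3842 and 1838 of its reads, and without these 2 libraries the log2 fold change was 1.29 (SE 0.29, adjusted p 0.538). The neighbouring chr7:144038490-144040019 (2.87) and chr15:58146063-58146362 (1.11) came next, both with an adjusted p of 1. In vehicle rats the smallest p were at chr4:539382-539651 (-1.84) and at both chromosome 7 regions (3.81 and 3.99). In corticosterone rats they were at chr1:36361130-36361422 (1.23), chr11:79710582-79710944 (1.26) and chr7:12327386-12327828 (-0.98), and for the interaction at chr1:187609396-187609765 (1.73), chr4:539382-539651 (2.1) and chr11:79710582-79710944 (1.61). None of the adjusted p for these separate effects and the interaction lay below 0.999. Both calls of DESeq2 for the average were these chromosome 7 regions (adjusted p 0.0129 and 0.0413). Without pCREB trained vehicle A, 3 regions were called for training in vehicle rats, among them both chromosome 7 regions (adjusted p 0.00169 for each), and 3 for the average, again with both (0.000489 and 0.0011). Without pCREB trained corticosterone A 3 were called in vehicle rats, including both (0.0291 for each).

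In simulated counts with the depth and spread of these libraries, the test recovered 60% of 2-fold and 98% of 4-fold changes for the average corticosterone effect on GR, and 71% and 100% for that on pCREB. For the average training effect the shares were 57% and 98% for GR and 76% and 100% for pCREB. For the corticosterone effect in untrained rats alone they were 21% and 85% for GR and 29% and 96% for pCREB. The counts were drawn independently for each region, without the shifts that regions share between the real libraries, so that real recovery may be lower. The changed regions were picked at random. For the average corticosterone effect on GR, the median SE was 0.357 at regions outside pCREB regions and 0.256 over all tested regions.

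How far GR and pCREB share binding sites was read from the overlap of the region lists. Of the 5307 GR regions 4253 overlapped a pCREB region by at least 1 bp, a share of 80.1% (95% exact Clopper-Pearson interval 79% to 81.2%). Seen from the pCREB list, 4243 of 14722 regions overlapped a GR region, a share of 28.8% (28.1% to 29.6%). When the GR regions were shifted along their chromosomes in 100 random placements, 0.718% overlapped a pCREB region on average and at most 1.02%. Such placements do not model background common to both antibodies. Since enrichment over input was not analysed, the overlap cannot tell such background from shared binding. GR regions that overlapped were wider than those that did not, with median widths of 421 bp and 309 bp.

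The strength of GR against pCREB signal was compared at 4225 regions shared one to one between both lists, per kb of region width. GR signal was higher at 191 and lower at 229 regions, in a fit without a term for the chromatin pool that both antibodies share. Among the named regions, GR signal was highest against pCREB at chr10:68863412-68863783, with 1850 ± 834 CPM per kb for GR and 249 ± 91.2 CPM per kb for pCREB (SD, n = 16 each, 7.05-fold, adjusted p 1.49e-12 by edgeR). Next was chr5:74507825-74508182, with 1410 ± 907 and 247 ± 97.1 CPM per kb (5.24-fold, adjusted p 1.09e-07 by edgeR). Among the named regions it was lowest at chr12:503395-503687, with 550 ± 215 CPM per kb for GR and 2410 ± 830 CPM per kb for pCREB (log2 fold change -2.16, SE 0.17, adjusted p 1.47e-15 by edgeR). Lower GR than pCREB signal was also found at chr14:10580909-10581163 (log2 -1.8), chr6:9482406-9482708 (-1.8), chr1:80920716-80921001 (-1.7), chr5:63781489-63781877 (-1.66) and chr20:3422054-3422268 (-1.02). DESeq2 called 213 higher and 229 lower. Signal is relative to the total over the shared regions, so that the balance of higher and lower depends on the scaling: scaling by total count gave 130 higher and 376 lower, and normalization before the correction for region width gave 964 higher and 96 lower. Without any width correction, the model as written before the data were examined, 1088 regions were called, 488 higher and 600 lower.

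Whether corticosterone acted differently on both factors was tested at the same 4225 regions. The difference between the corticosterone effects on GR and on pCREB passed at 0 regions in edgeR (287 at an unadjusted p under 0.05, 211 expected by chance) and at 0 in DESeq2. The regions with the smallest p were chr8:110500321-110500543 (log2 difference 1.6, SE 0.36, adjusted p 0.15), chr4:111181535-111181818 (1.55, SE 0.37, adjusted p 0.174) and chr8:53839651-53840128 (1.24, SE 0.31, adjusted p 0.281). Without GR untrained vehicle B 5 regions were called and without pCREB trained vehicle D 1 region, and with the chromatin pool as a replicate block 2 were called. In simulated counts drawn independently for each region, the test recovered 58% of 2-fold and 97% of 4-fold differences. It covers only regions that both antibodies share, and 72 of the 82 regions with a GR rise lie outside the pCREB list.

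Total reads in the listed regions differed with corticosterone for GR. The geometric mean was 1.353-fold higher in the 8 corticosterone than in the 8 vehicle GR libraries (two-sided exact permutation test, p 0.005439). The ratio of trained to untrained GR libraries was 1.201 (exact permutation p 0.1742). For pCREB the ratios were 0.935 for corticosterone and 0.962 for training (exact permutation p 0.7392 and 0.8544). Library totals reflect sequencing depth as well as binding, and the GR list itself holds 4500 regions called in 3 or more trained corticosterone libraries and 321 called in 3 or more untrained vehicle libraries. In addition, each condition was sequenced in its own lane, so that lane and condition cannot be told apart.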

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

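The tests in this part were chosen after the results they concern had been seen, except the splits of the libraries. For the covariate test, the listing test and the median over shared regions in the weighed patterns, the meaning of each outcome was written down beforehand.

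Read totals, numbers of called regions and signal at the named regions were compared within 200 groups of 4 libraries. In 9 of these, all at named regions, 1 library stood far from the other 3, and about 10 such groups are expected by chance. At chr17:5971448-5971815 GR untrained vehicle D had a log2 CPM of 6.93 against 5.36 to 5.62 in the others of its group, and GR trained corticosterone A had 7.97 against 8.35 to 8.42. GR trained corticosterone D had 9.07 at chr1:78999395-78999862 (others 8.89 to 8.91), GR trained corticosterone A had 6.07 at chr10:75291146-75291478 (others 6.78 to 6.87), and GR trained corticosterone C had 7.61 at chr8:53839651-53840128 (others 8.49 to 8.55). Among pCREB libraries, trained vehicle C had 6.16 at chr1:36361130-36361422 (others 5.42 to 5.54) and trained vehicle D had 4.39 at chr4:71120929-71121446 (others 5.15 to 5.25). Trained vehicle B was low for both antibodies at overlapping regions, with 5.61 for GR at chr11:79710601-79710854 (others 6.56 to 6.71) and 4.25 for pCREB at chr11:79710582-79710944 (others 5.7 to 5.74).

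The first pattern is that 72 of the 82 GR regions that rose after corticosterone lay outside pCREB regions. Read depth and region width are argued against as the cause, since overlapping regions matched on both had a median log2 fold change of -0.05 (-0.1 to -0.01 in 10000 draws) against 0.48 outside, and the fold changes outside were less precise (median SE 0.36 against 0.27). Differences in enrichment between libraries are argued against only as far as they show at the overlapping GR regions. With the first principal component of those regions as a covariate, all 82 regions stayed past the threshold, and their median log2 fold change went from 1.63 to 1.57. Calls increased to 232 higher, 200 of them outside pCREB regions, and 8 lower. Enrichment that differs only outside the overlapping regions, or that follows condition, is not removed by this covariate and stays open. The geometric mean of total GR reads was 1.353-fold higher in corticosterone libraries. The listing of regions by calls in these same libraries stays open, because in libraries that took no part in the listing the gap between outside and overlapping regions widened with corticosterone by 0.61 (SE 0.5, exact permutation p 0.314, untrained) and 0.55 (SE 0.26, exact permutation p 0.0571, trained), sizes like the full effect but with too few libraries to exclude 0. The corticosterone treatment stays open as the biological explanation and was not tested apart from lane, since lane and condition cannot be told apart.

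The second pattern is at the 9 tested pCREB regions that overlap a risen GR region, where pCREB signal was higher after corticosterone in 9 of 9 (median log2 fold change 0.43, range 0.25 to 0.74; camera p 7.87e-08, p = 0.00141 with an estimated correlation, fry p 0.00108), although the smallest adjusted p of a single region was 0.84. A rise of all shared regions is argued against by the median of 0.063 over all pCREB regions that overlap a GR region. A chance draw of regions of like abundance is argued against by the 0.04% of matched sets with a median as high. The draws took regions independently, although the 9 had an estimated correlation of 0.104. Both antibodies also share their pools, so that chance variation between pools stays open. GR reads in the pCREB libraries of the same pools stay open. At most 4.11% of GR reads can sit there, judged by 3 pools, and the rise needs 9.94% (SE 2.11), with 3.69% to 22.8% in single pools. The corticosterone treatment itself stays open here too, untested.

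The third pattern is a cluster of neighbouring regions on chromosome 7, chr7:144015886-144017606, chr7:144038895-144039988 and chr7:144040559-144041164 in the GR list, that held up to 4809 reads in single GR libraries (median 323) and up to 3842 in single pCREB libraries (median 118). In the 7 libraries with 1560 or more reads in the largest of them, 5 of GR and 2 of pCREB, the log2 ratio of the 2 largest regions had an SD of 0.028 around 1.51, which is consistent with DNA of a single source entering single libraries. Training is argued against as the cause of the high GR reads, because GR untrained vehicle D and untrained corticosterone B held 4607 and 4602 reads, about as many as GR trained vehicle D and trained corticosterone B with 4518 and 4809. For pCREB training stays open. At chr7:144015523-144017621 pCREB libraries held 63 to 113 reads in untrained vehicle and 25 to 92 in untrained corticosterone rats. Trained vehicle libraries held 123 to 3842 and trained corticosterone libraries 151 to 196. Without pCREB trained vehicle B and D the log2 fold change of the training effect on pCREB went from 3.02 to 1.29 (SE 0.29, adjusted p 0.538 by edgeR). These libraries were left out for their high reads, so that a fall was fixed in advance and does not count against training. All 7 libraries carried the letter B or D, which was seen afterwards and was not tested. No value showed where such DNA came from.

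Other splits of the libraries into groups of the same sizes were counted for each comparison. The real split gave the most calls for the average corticosterone effect on GR (83, 1 of 100 splits, highest other 59). It also did so for that in trained rats (6, 1 of 35, highest other 0) and for GR against pCREB (420, 1 of 100, highest other 92). Regions were listed by calls within the real conditions, which favours the real split of conditions in advance. With at most 100 splits for each of many comparisons, chance is not excluded for these counts. For the corticosterone effect on GR in untrained rats, 3 of 35 splits gave 15 or more calls, with 701 in another split, so that chance cannot be excluded; that count points to a structure of the samples other than treatment. Where the real count was 0, every split gives at least as many calls, so that the count says nothing against chance. This held in 100 of 100 splits for the GR training effect (highest other 32), the GR interaction (7), the difference of corticosterone effects (0) and the pCREB average corticosterone effect (613), training effect (2017) and interaction (1894). It held in 35 of 35 splits for the GR training effects in corticosterone (0) and vehicle rats (162), and for pCREB corticosterone in untrained (0) and trained rats (3349) and training in corticosterone (1) and vehicle rats (2543). Splits with many pCREB calls point to a structure of the pCREB libraries that does not follow the conditions.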

How the results depend on the processing

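No named region changed direction under any alternative run. The balance of GR against pCREB did, from 191 higher and 229 lower to 964 and 96 with TMM before the width correction, and both pCREB read ratios, which did not pass their tests, crossed 1 without pCREB trained corticosterone A (1.076 and 1.11). Surrogate variable, covariate, few-call, loess, shared-TMM, list-restricted and TMM-before-width settings were added after seeing the data, as was the overlap of the regions with most calls. The GR corticosterone counts (15 in untrained rats, 6 in trained rats, 83 for the average) kept their direction but not their size, and unless stated the cause was not tested. In that order they were 24, 22 and within 1.5 times with DESeq2; 41, 27 and 125 with scaling by total count; 40, 18 and 199 without the libraries with few calls; 135, 42 and 167 with 1 surrogate variable; and 181, 46 and 240 with the first principal component of the regions shared with pCREB as a covariate. A stricter adjusted p of 0.01 gave 7, 3 and 46. Adjustment over regions outside pCREB regions gave 71, 39 and 149. This class was taken after seeing the data, which favours more calls in advance. For the average, 284 of its 904 regions had an unadjusted p under 0.05, against 619 of all 4968. Fits of only the groups compared gave 0 in untrained and 56 in trained rats, the reverse of the order in the main fit. They have fewer samples, which does not account for the higher count in trained rats. In untrained rats loess offsets gave 9 and TMM from shared regions 8. Whether letters pair the libraries was not settled. With the letter as a replicate block the counts were 46, 32 and 125, and no other GR or pCREB count changed. With the chromatin pool as a replicate block, the difference of corticosterone effects had 2 calls.

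GR training gave 1 call, chrX:47422884-47423119, with DESeq2, with total count scaling, with a surrogate variable and with the covariate (average), and 1 other region in vehicle rats with a surrogate variable. The pCREB training average gave 2 in DESeq2, and training in corticosterone rats 1 with only the groups compared. GR against pCREB gave 1060 calls with TMM before the width correction and 1088 (488 higher, 600 lower) with none; the latter is the model as written before the data were examined, and it became an alternative only when widths were seen to differ between lists (median log2 ratio -0.192). Among regions with most calls, 78.4% of GR and 27.6% of pCREB regions overlapped; the file holds no peak score.

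Leaving out 1 library gave 5 to 225 calls for corticosterone on GR in untrained rats, 3 to 29 in trained rats and 53 to 335 for the average, with at least 52 of the 83 kept. It gave 0 to 1 for average training on GR, 0 to 3 for pCREB training in vehicle rats and on average, 0 to 5 for the difference of corticosterone effects, 366 to 444 for GR against pCREB and 0 for all others. Read ratios stayed within 1.25 to 1.395 (GR, corticosterone), 1.1 to 1.256 (GR, training), 0.859 to 1.076 and 0.886 to 1.11 (pCREB). Over all alternatives, the 63 named results at single regions, some of them for the same region in other comparisons, had 1873 repeats, of which 1807 kept their side of the threshold, 49 lost it and 17 gained it; the 10 regions of the average GR effect kept it in all 279. Not run, for lack of inputs, genome or annotation here: background TMM, leaving out regions high in input, and gene list and motif settings. At this depth simulated 2-fold changes were recovered less often than 4-fold ones, except for GR against pCREB.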

Other observations

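The tests in this part were chosen after the results were seen.

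At a pair of sites, GR and pCREB signal both had one of the 3 smallest p for training in corticosterone rats, although neither site passed for either antibody. The sites were picked for their small p. Both antibodies were used on the same chromatin pools, so that their signals are not independent, and how often such a match arises by chance was not tested. At chr1:36361139-36361388 the log2 fold change for GR was 1.37 (SE 0.33, adjusted p 0.777), and at the overlapping chr1:36361130-36361422 it was 1.23 for pCREB (SE 0.3, adjusted p 1). At chr11:79710601-79710854 it was 1.81 for GR (SE 0.45, adjusted p 0.777), and at the overlapping chr11:79710582-79710944 it was 1.26 for pCREB (SE 0.33, adjusted p 1).

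The 82 GR regions that rose after corticosterone were looked at for training as a set. Their median log2 fold change for training was -0.31 in corticosterone rats (6 of 82 higher in trained rats; camera p 8.46e-07, but p = 0.325 with an estimated correlation and fry p 0.391) and -0.17 in vehicle rats (29 of 82 higher; camera p 0.0453, p = 0.682 with an estimated correlation, fry p 0.733). The regions move together between libraries (estimated correlation 0.507 and 0.502), so that the preset p overstates the evidence, and these regions were chosen on the same libraries.

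Over all 904 tested GR regions outside pCREB regions, 740 had a higher GR signal after corticosterone (median log2 fold change 0.48; camera p 4.25e-44, p = 0.0189 with an estimated correlation, fry p 0.0314). After adjustment over the 7 comparisons tested for this set, the values were 0.132 with an estimated correlation and 0.22 for fry, so that the shift of this class does not pass.

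It was asked whether sites that respond together may lie close together. Among the 82 regions there were 4 neighbouring pairs within 100 kb, where random draws with the same pCREB overlap gave 2.03 on average and 5 at the 95th percentile (permutation p 0.16), which leaves the question open. One of the pairs joins chr17:5921215-5921492 to the strongly risen chr17:5971448-5971815, with a gap of 49956 bp, and another lies at chr13:71575065-71575656 and chr13:71606937-71607641.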
